A study of Mus musculus with 8 samples.

How the data were processed

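The data are bulk RNA-seq libraries from mouse tumours. Tumours were grown under the skin of C57BL/6 mice from B16-F10 cells, a mouse melanoma line, in which the Pten gene had been knocked out, and the mice received an injection of PTEN protein or of phosphate-buffered saline (PBS) every day for 7 days, per the labels. The injection was into the tumour or into the peritoneum, and which of these routes each mouse received is not given in the sources used here. The series' design text speaks of single-cell sequencing, whereas the labels' protocols describe poly-A selected RNA of whole tumour pieces, and each file holds 1 value per gene and library, so the libraries were treated as bulk.

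Files of counts and of FPKM were used for each of the 8 libraries. The deposited read counts are whole numbers per Ensembl mouse gene, not normalized. The deposited FPKM values are normalized by gene length and library total, per the file headers and the values. Dividing the counts by the FPKM and by the library's total count gave the same gene length in every library, to a largest relative deviation of 1.64e-07. The submitters' processing notes name fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so no genome coordinates are printed. Reads of overlapping or antisense genes may have been counted together. Genes with near-identical or related copies (alpha and beta globin genes, ribosomal protein genes, Gsdmc, Ifit3b, Saa3) may have less certain counts. Each file holds 21899 genes, of which 21795 matched a symbol and 104 did not; the latter took at most 0.111% of a library's counts. No line held a total or unassigned reads.

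Libraries were grouped by sample title, which gives 4 PBS and 4 PTEN libraries. The treatment label of the same samples contradicts the title for 3 of them: PBS replicate 4 carries a PTEN treatment label, and PTEN replicates 3 and 4 carry a PBS treatment label. Nothing in the sources used here says which label is right, and expression values were not used to decide. The alternative groupings were therefore fixed before the data were examined, 1 by the treatment label (5 PBS and 3 PTEN libraries) and 1 with only the libraries whose labels match (3 PBS and 2 PTEN). Nothing in the labels says that each library came from a different mouse, so p-values measure the spread between these samples.

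Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 12257 genes. Library sizes were scaled by TMM, and groups were compared with the robust quasi-likelihood F test. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are PTEN minus PBS; standard errors were derived from the fold change and the F statistic. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD over 4 libraries. For genes below the filter, the ratio of summed counts is given with an exact 95% interval. This interval covers counting error only and leaves out the spread between libraries. Reads copied by PCR are also not independent molecules.

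Before the data were examined, 37 gene lists were fixed (pathways, cell type markers and signs of RNA quality). The 34 with at least 5 tested members were tested with limma 3.58.1 camera at its preset correlation of 0.01 between genes, adjusted over the 34 lists. The correlation estimated from the data, limma's fry and a replicate-level test were run beside it. In the last, the level of a list in a library was the mean of its members' log2 CPM (prior count 2), each standardized over the 8 libraries, and groups were compared by an exact two-sided permutation test over all assignments of 4 and 4, whose smallest p is 0.0286. The same exact test was used for totals, detected genes and principal components.

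The genes named were chosen by a rule fixed before the data were examined: 14 genes tied to the study's question whatever their values; the 10 largest fold changes in each direction among called genes with an official symbol, a mean of at least 1 CPM and no overlap between groups, or, where fewer than 5 passed, the 5 with the smallest p under the same rule without the adjusted p; and up to 4 members with the smallest p in each list. Genes named outside this rule are marked as such.

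Alternatives within edgeR were the other groupings, a block on replicate number, DESeq2 size factors, upper quartile scaling and library totals. Others were no filter, a filter of 5 CPM in 4 libraries and a further threshold of 1 on the log2 fold change. Other tests were DESeq2 1.42.0, limma voom with quality weights, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) after a filter on a mean FPKM of 1, the former also without it. Each library was also left out in turn. The procedure was tested on simulated data made from these libraries' means, sizes and fitted dispersions over 12257 genes, each gene drawn independently. For PTEN against PBS with 4 and 4 simulated libraries, edgeR recovered 81 of 100 genes changed 2-fold and 98 of 100 changed 4-fold. Of its calls 5.58% were unchanged genes, against 13.1% of the calls made by DESeq2. Genes of a list vary together in the real libraries, which the simulation leaves out. On the real counts DESeq2 tested 16253 genes. These shares therefore need not hold for the real data. No library pair of a group was a duplicate: chi-square per degree of freedom between such libraries ran from 6.27 to 21.8.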

Results

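Gene expression was measured by bulk RNA-seq in 8 libraries from subcutaneous tumours grown in mice from B16-F10 melanoma cells labelled as Pten knockout, after 7 days of daily injections of PTEN protein or PBS. The comparison asks how tumour gene expression differs when PTEN protein, a lipid phosphatase that opposes PI3K signalling inside cells, is supplied from outside. By sample title, 4 libraries were PBS and 4 were PTEN. The treatment label contradicts the title for PBS replicate 4 and for PTEN replicates 3 and 4, so every direction given here is that of the titles. Total counts ran from 14685770 to 16460722 per library and did not differ detectably between groups (exact two-sided permutation p = 0.543). Between 14375 and 14639 genes had a count, and the 10 most abundant genes took 6.64% to 7.24% of the counts. The first principal component held 24.9% of the variance and did not separate the groups (exact permutation p = 0.114).

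Pten transcript (ENSMUSG00000013663) was present in every library, at 70.6 ± 7.10 CPM in PBS and 68.5 ± 5.77 CPM in PTEN libraries (SD, n = 4 each). The log2 fold change was -0.04 (SE 0.09; edgeR adjusted p = 0.933). The cells are labelled Pten knockout in both groups, so this level does not check the group labels. Gene-level counts do not bear out the knockout label and cannot check it, since they do not show whether the transcript is intact or which cells it came from. Plxdc2, a cell-surface protein that has been described as a receptor for secreted PTEN, was at 4.13 ± 0.71 CPM in PBS and 4.92 ± 1.22 CPM in PTEN libraries (log2 fold change 0.25, SE 0.23, adjusted p = 0.817). Tmed10, a cargo receptor of the secretory pathway, was at 397.0 ± 9.27 and 389.3 ± 9.69 CPM (adjusted p = 0.935). The list of genes of the secreted PTEN route was not called (13 members tested, median log2 fold change 0.01, camera adjusted p = 0.580). The lists of PI3K and AKT pathway parts (30 members, median 0.07, camera adjusted p = 0.2) and FOXO target genes (23 members, median 0.06, mean -0.03, camera adjusted p = 0.907) were not called either.

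In edgeR, Marco and Slc13a3 rose in the PTEN libraries, and no gene fell. Marco (ENSMUSG00000026390), a scavenger receptor of macrophages that binds bacterial surfaces, was at 0.21 ± 0.16 CPM in PBS and 3.33 ± 1.17 CPM in PTEN libraries, a 15.4-fold difference (log2 fold change 3.95, SE 0.52, edgeR adjusted p = 0.0158). Slc13a3 (ENSMUSG00000018459), a sodium-coupled transporter of dicarboxylates, was at 0.27 ± 0.11 and 2.65 ± 0.73 CPM, a 9.44-fold difference (log2 fold change 3.24, SE 0.40, adjusted p = 0.0158). All 4 PTEN libraries lay above all 4 PBS libraries for both genes. Both are low-abundance transcripts: Marco had 13 counts in the PBS libraries together and 213 in the PTEN libraries, and Slc13a3 had 17 and 169. With groups by title, 2 of 12257 tested genes were called, against 0 of 12418 by the treatment label and 7 of 12500 with only the libraries whose labels match. Of these 7, 1 (Marco) was among the 2. At an unadjusted p under 0.05 there were 882 genes by title (475 higher, 407 lower) and 116 by the treatment label. With groups by title, DESeq2 called 3 genes lower where edgeR called 0. Neither gene was called without PBS replicate 2 (edgeR adjusted p = 0.0989 for both), where log2 fold changes were 4.04 for Marco and 3.30 for Slc13a3. Both calls were also lost without PBS replicate 3 (0.141 for Slc13a3, 0.154 for Marco) or PTEN replicate 1 (0.0741 for both). Marco was not called without PTEN replicate 2 (adjusted p = 0.0552). Without PTEN replicate 4, 8 genes were called.

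**Figure D1:**
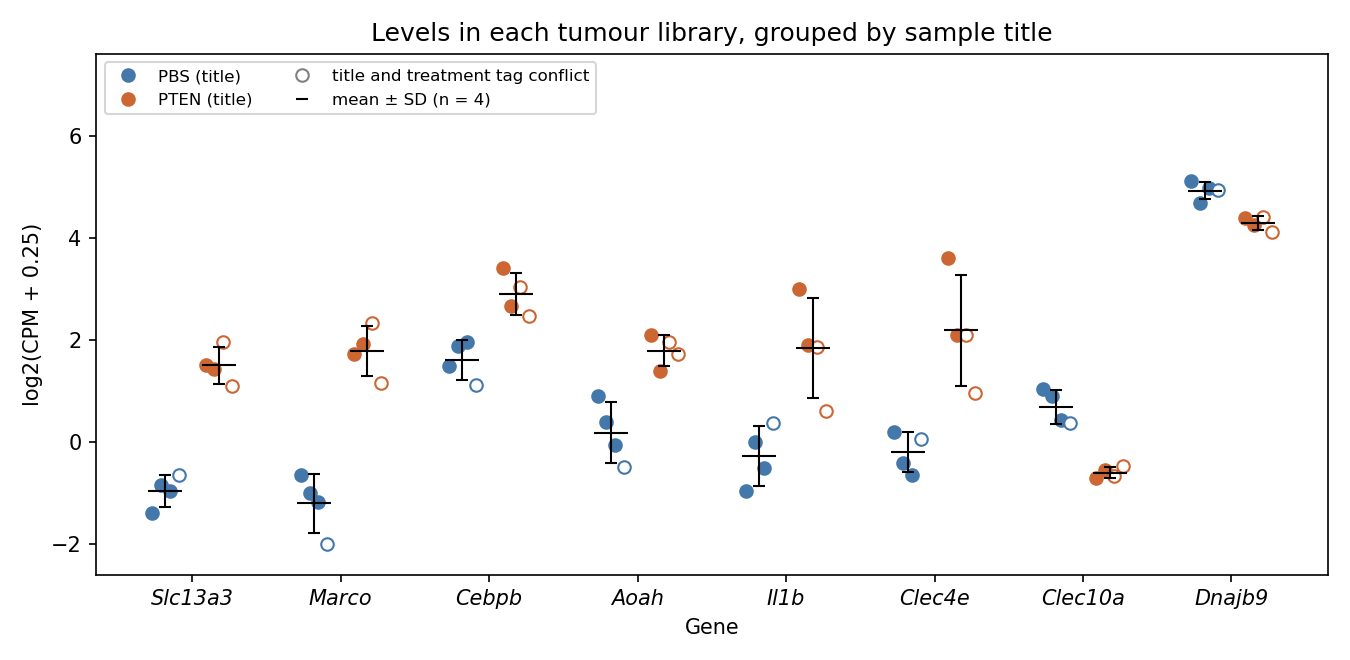
Level of 8 genes in each library, as log2(CPM + 0.25), with PBS libraries in blue and PTEN libraries in orange by title; bars are the mean ± SD of the plotted values (n = 4) and hollow points mark the 3 libraries whose title and treatment label conflict. Marco runs from 0 to 0.39 CPM in PBS and from 1.96 to 4.78 CPM in PTEN libraries, Clec10a lies lower in all 4 PTEN libraries, and of the genes drawn Marco and Slc13a3 pass the adjusted threshold.

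Other genes separated the groups without passing the threshold. Cebpb, a transcription factor of myeloid cells, was at 2.89 ± 0.80 CPM in PBS and 7.43 ± 2.27 CPM in PTEN libraries (log2 fold change 1.36, SE 0.26, edgeR adjusted p = 0.273). Also higher in all 4 PTEN libraries were Aoah, an enzyme that inactivates bacterial lipopolysaccharide (1.75, SE 0.36, adjusted p = 0.399) and Rnf213, an interferon-inducible ubiquitin ligase (0.42, SE 0.08, adjusted p = 0.249). Dnajb9, a chaperone of the endoplasmic reticulum, was at 30.3 ± 3.59 and 19.4 ± 1.85 CPM (-0.64, SE 0.11, adjusted p = 0.153) and lower in all 4 PTEN libraries. So were Prom1 (-1.10, SE 0.27, adjusted p = 0.496), Hmga2, a chromatin protein (-0.54, SE 0.13, adjusted p = 0.531), Gsdmc (-0.40, adjusted p = 0.496) and Tmem263 (-0.38, adjusted p = 0.501). In all, 487 genes had groups that did not overlap, 3.97% of those tested, against 2.86% by chance. DESeq2 called 26 genes, 23 higher and 3 lower, among them Marco, Slc13a3, Rnf213, Cebpb, Aoah and Dnajb9.

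Lists of inflammatory and myeloid genes were called higher in PTEN libraries. Inflammatory (M1-type) macrophage genes had a median log2 fold change of 0.41 (14 members tested, 11 with a higher estimate, camera adjusted p = 3.63e-07). Neutrophil markers (7 of 22 listed members tested, 6 higher, median 1.29, adjusted p = 1.91e-06) and NF-kB inflammatory genes (20 members, 15 higher, median 0.12, adjusted p = 9.83e-05) were called as well. So were macrophage and monocyte markers (22 members, 22 higher, median 0.40, adjusted p = 3.74e-08). With an estimated correlation none of these calls held (adjusted p = 0.632 for each). Exact permutation of the list levels gave p = 0.171, 0.0857, 0.171 and 0.171 in the same order. In edgeR 1 M1-type gene, Marco, rose over all genes, and adjusted over the list alone 3 did: Marco, Il1b (log2 fold change 2.65, SE 0.55) and Acod1, the enzyme that makes itaconate (3.23, SE 0.75). Adjusted over the list alone, 3 of the neutrophil list rose: Clec4e, a receptor for mycobacterial glycolipids (3.06, SE 0.60), Mmp9 (2.29, SE 0.57) and Clec4d (1.29, SE 0.40). Of the NF-kB list, 3 rose adjusted over the list alone: Il1b, Icam1 (1.17, SE 0.31) and Ccl3 (1.80, SE 0.50). Over all genes, 0 of either list passed in edgeR. DESeq2 called Il1b (adjusted p = 0.00132), Acod1 (0.0315), Clec4e (1.65e-05) and Mmp9 (0.0179) higher over all genes. Clec4e, Clec4d and Mmp9 are also made by activated macrophages. No macrophage marker passed either way in edgeR, while DESeq2 called Cd14 (adjusted p = 0.0413) and Adgre1 (0.0494) higher. Cd14 (1.57, SE 0.42), Lyz2 (1.25, SE 0.30) and Adgre1 (1.27, SE 0.37) were higher in all 4 PTEN libraries (edgeR adjusted p = 0.633 to 0.677), and Ms4a7 had 1.36 (SE 0.44). C1qa, C1qb and C1qc, complement genes of tissue macrophages named outside the fixed rule, had 0.10, 0.15 and 0.10. At the preset correlation of 0.01 the 4 list calls held when any single library was left out, but their medians moved. The correlation estimated from the data was 0.61 for macrophage, 0.37 for M1-type, 0.36 for neutrophil and 0.32 for NF-kB genes. Without PTEN replicate 1 the macrophage median was 0.18, the NF-kB median 0.05 and the neutrophil median 0.83. Without PBS replicate 1 the macrophage and M1-type medians were 0.65 and 0.67, without PBS replicate 2 the M1-type median was 0.65 and the NF-kB median 0.19, and without PBS replicate 3 the M1-type median was 0.27. The macrophage median was also 0.61 without PTEN replicate 2, and the NF-kB median 0.20 without PTEN replicate 4. The NF-kB call was lost under a filter of 5 CPM in 4 libraries (adjusted p = 0.424), and the macrophage list turned to a median of -0.09 by the treatment label.

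Among the fixed inflammatory genes, Nos2, which makes nitric oxide, was at 4.37 ± 1.39 CPM in PBS and 10.8 ± 8.30 CPM in PTEN libraries (log2 fold change 1.30, SE 0.59, edgeR adjusted p = 0.691); without PTEN replicate 1, which had 21.9 CPM, the log2 fold change was 0.68. Arg1, an enzyme of alternatively activated macrophages, was at 18.6 ± 5.17 and 13.9 ± 11.2 CPM (-0.42, SE 0.66, adjusted p = 0.912), and -0.95 without PTEN replicate 1 but -0.09 without PTEN replicate 4. Tnf, Il6 and Ifng were below the filter of the edgeR fit; DESeq2 called Tnf higher (adjusted p = 0.0203). Tnf had 9 counts in the PBS and 90 in the PTEN libraries, a ratio of 9.77 (exact 95% interval 4.93 to 22.1), with all 4 PTEN above all 4 PBS libraries. Il6 had 2 and 14 counts (ratio 6.84, exact 95% interval 1.57 to 62.0), with groups that overlapped, and Ifng 0 and 2, too few for a ratio. These intervals leave out the spread between libraries. The list of alternative (M2-type) macrophage genes was called lower (14 members, 9 lower, median -0.15, camera adjusted p = 0.0396; adjusted p = 0.632 with an estimated correlation). Over all genes 0 of its members fell, and adjusted over the list alone 2 did: Clec10a, a galactose-binding lectin (1.40 ± 0.37 and 0.41 ± 0.05 CPM, log2 fold change -1.75, SE 0.38), and Spp1, osteopontin (-0.42, SE 0.11). Mrc1 (-0.61, SE 0.23) and Stab1 (0.64, SE 0.25) pointed apart. This call was lost without PBS replicate 1 or 2 or PTEN replicate 2 or 4. It was also lost with the replicate number as a block (camera adjusted p = 0.0598), by the treatment label (0.0657) and under the filter of 5 CPM (0.261). Over the 8 fits without 1 library its median ran from -0.28 to -0.02.

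Interferon and antigen presentation lists were called higher at the preset correlation, with 0 members passing over all genes or adjusted over the list alone. They were the type I interferon response (30 members, 27 higher, median 0.19, camera adjusted p = 0.00144), MHC class I presentation (22 members, 22 higher, median 0.32, adjusted p = 0.00563) and the interferon gamma response (26 members, 22 higher, median 0.43, adjusted p = 0.0158). With an estimated correlation they gave adjusted p = 0.632, 0.632 and 0.708. Irf7 had a log2 fold change of 0.66 (SE 0.34), Nlrc5, an activator of MHC class I genes, 0.57 (SE 0.38), and Ifit3b 0.58 (SE 0.23). PTEN replicates 1 and 3 had the highest type I interferon levels (1.30 and 0.87) and PTEN replicates 2 and 4 had levels of -0.35 and -0.86, within or below the PBS range of -0.49 to 0.47. Each of these 3 calls was lost without PTEN replicate 1 and without PTEN replicate 3, where the median of the type I list was 0.09 and 0.12, that of the MHC class I list 0.27 and 0.08, and that of the interferon gamma list 0.22 and 0.11. The MHC class I and interferon gamma calls were also lost without PBS replicate 3 (medians 0.16 and 0.30), and the latter without PBS replicate 2 (0.32). Medians were larger without PTEN replicate 2 (0.50 for MHC class I, 0.66 for interferon gamma), without PTEN replicate 4 (0.64 for interferon gamma, 0.29 for type I) and without PBS replicate 1 (0.65 for interferon gamma). The interferon gamma call was lost by the treatment label (adjusted p = 0.345), where the MHC class I median turned to -0.12 (0.0579); with matching labels only the MHC class I call was lost (0.202).

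Lymphocyte genes were sparse, and no list of them was called. Cd8a was at 0.67 ± 0.77 CPM in PBS and 0.73 ± 0.37 CPM in PTEN libraries (edgeR adjusted p = 0.985), and Gzmb, a granule protease of cytotoxic cells, at 3.58 ± 3.08 and 3.40 ± 2.77 CPM (adjusted p = 0.992). T cell markers (5 members, median -0.02, camera adjusted p = 0.907) and cytotoxic lymphocyte and NK cell markers (8 members, median 0.01, mean -0.05, 0.580) did not pass. T cell exhaustion and checkpoint genes (11 members, median 0.00, mean 0.11, 0.584), dendritic cell markers (11 members, median 0.12, 0.201) and MHC class II presentation (10 members, median 0.00, 0.605) did not pass either. The checkpoint ligand Cd274 was at 19.3 ± 2.07 and 19.1 ± 6.16 CPM (adjusted p = 0.992). B cell and mast cell lists had 3 and 2 tested members, too few to test, as did skin epithelium with 2.

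Of the lists of tumour cell genes, the invasive melanoma list was called and the pigment and cell cycle lists were not. Mitf, the master regulator of pigment cells, was at 800.5 ± 49.1 CPM in PBS and 840.5 ± 87.4 CPM in PTEN libraries (log2 fold change 0.07, SE 0.08, edgeR adjusted p = 0.861). Tyr, the first enzyme of melanin synthesis, was at 913.8 ± 66.9 and 930.3 ± 23 CPM (adjusted p = 0.952), and the proliferation gene Mki67 at 142.7 ± 45.6 and 147.6 ± 57.8 CPM (adjusted p = 0.984). Melanoma and pigment genes (24 members, median 0.05, camera adjusted p = 0.122) and the cell cycle list (35 members, median -0.03, adjusted p = 0.284) were not called. Trpm1, a cation channel of pigment cells, was at 1098 ± 118.5 and 1300 ± 63.6 CPM and higher in all 4 PTEN libraries (0.24, SE 0.08, adjusted p = 0.677). The list of invasive melanoma genes was called lower (16 members, 13 lower, median -0.19, camera adjusted p = 0.0158; adjusted p = 0.632 with an estimated correlation), with Sparc at -0.18 (SE 0.08) and Axl at 0.36 (SE 0.24). It was not called without PBS replicate 2 or PTEN replicate 2 or 4 (median -0.11 without the last), by the treatment label (adjusted p = 0.935) or with matching labels only (0.0920).

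Metabolic and stress lists were called at the preset correlation as well. Glycolysis and hypoxia genes were called lower (27 members, 25 lower, median -0.18, camera adjusted p = 9.83e-05), with Mxi1 at -0.36 (SE 0.11) and Ndrg1 at -0.51 (SE 0.21). Heat shock and unfolded protein response genes were called lower (26 members, 18 lower, median -0.14, adjusted p = 0.00206). In edgeR 1 fell adjusted over the list alone, Dnajb9, against 0 over all genes, where DESeq2 called Dnajb9 lower (adjusted p = 0.000588), and Hspa8 had -0.34 (SE 0.14). p53 targets (18 members, 12 lower, median -0.04, adjusted p = 0.0460) and immediate early genes (19 members, 16 lower, median -0.09, adjusted p = 0.0387) were called lower, with Cdkn1a at -0.42 (SE 0.14) and Myc at -0.21 (SE 0.10). Cholesterol and fatty acid synthesis was called higher (28 members, 24 higher, median 0.15, adjusted p = 0.00697), with Fasn at 0.25 (SE 0.11). With an estimated correlation all 5 calls were lost (adjusted p = 0.632 for the first 4 and 0.701 for the cholesterol list). The glycolysis call was lost without PTEN replicate 4 (median -0.08), and its median was -0.11 without PBS replicate 2. The heat shock call was lost without PTEN replicate 3 (median 0.04), and its median was -0.04 without PBS replicate 3. Each of the other 3 was lost without at least 4 of the libraries in turn. The cholesterol median was 0.04 without PTEN replicate 3, 0.09 without PBS replicate 2 and 0.26 without PTEN replicate 1. The p53 median was -0.13 without PTEN replicate 1, -0.09 without PBS replicate 2 and -0.08 without PBS replicate 4 or PTEN replicate 2. The median of the immediate early genes was -0.03 without PTEN replicate 4, -0.16 without PBS replicate 4 and -0.21 without PTEN replicate 1. The glycolysis list was called higher by the treatment label (median 0.11, adjusted p = 0.00266) and the cholesterol list lower (-0.12, 4.6e-06), and the other 3 calls were lost. With matching labels only none of the 5 was called (adjusted p = 0.0920 for glycolysis, 0.949 for immediate early genes, 0.155 for p53 targets and 0.202 for the other lists).

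Ribosomal protein genes were called lower, with all 35 tested members estimated lower by a small amount (median log2 fold change -0.12, camera adjusted p = 2.27e-09; adjusted p = 0.632 with an estimated correlation; exact permutation p = 0.114 for the list level). The call was lost by the treatment label, where the median was -0.0065 (adjusted p = 0.901). Rpl6 was at 808.3 ± 66.0 CPM in PBS and 706.3 ± 11.6 CPM in PTEN libraries, and 0 members passed over all genes or adjusted over the list alone. PBS replicate 3 had the highest level of this list (1.65) and the lowest of macrophage markers (-1.23). PTEN replicate 1 had the lowest level of this list (-0.93) and the highest of macrophage markers (0.89). Mitochondrially encoded genes (10 members, median 0.04, adjusted p = 0.907) and histone genes without a poly-A tail (6 members, median -0.13, adjusted p = 0.2) were not called.

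Markers of other tissues varied from library to library. Red blood cell genes were called lower in PTEN libraries (7 members, 7 lower, median -2.14, camera adjusted p = 0.0387; adjusted p = 0.632 with an estimated correlation), but PBS replicate 4 alone had 1090 CPM of the beta globin Hbb-bs against 25.7 to 227 CPM in the other libraries. The call was lost without PBS replicate 3 or 4 or PTEN replicate 1 or 4, and the median was -0.41 without PBS replicate 4. The median turned to 1.85 by the treatment label (adjusted p = 0.0579), and with matching labels only the call was lost (0.202). Endothelial markers were called higher (24 members, 18 higher, median 0.19, adjusted p = 0.000952; adjusted p = 0.632 with an estimated correlation), with Kdr, a receptor for vascular endothelial growth factor, at 0.31 (SE 0.13) and Eng at 0.19 (SE 0.08). The call was lost without PTEN replicate 1 and by the treatment label (adjusted p = 0.178). Fibroblast and matrix genes (23 members, median -0.26, adjusted p = 0.0896) and pericyte and smooth muscle markers (13 members, median -0.23, 0.0925) were not called. Neither were skeletal muscle markers (8 members, median -0.63, 0.257), Schwann cell markers (11 members, median -0.08, 0.2) and adipocyte markers (7 members, median 0.18, mean 0.00, 0.907). Acta1, a muscle gene, was named outside the fixed rule. Muscle RNA was highest in PBS replicate 1 and PTEN replicate 4, with 51.7 and 18.3 CPM of Acta1 against 0.065 to 3.03 CPM elsewhere. Without these libraries, a setting chosen after the data were seen, Marco and Slc13a3 were again the 2 genes called, and 10 lists were called higher and 5 lower. By the treatment label, 4 of the 9 lists called higher by title stayed called higher (M1-type, neutrophil, NF-kB and type I interferon), and 0 of the 8 called lower stayed called lower. PTEN replicate 1, a PTEN library by either label, had the highest level of each of these 4 lists (1.05, 1.23, 1.15 and 1.3 in that order).

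**Figure D2:**
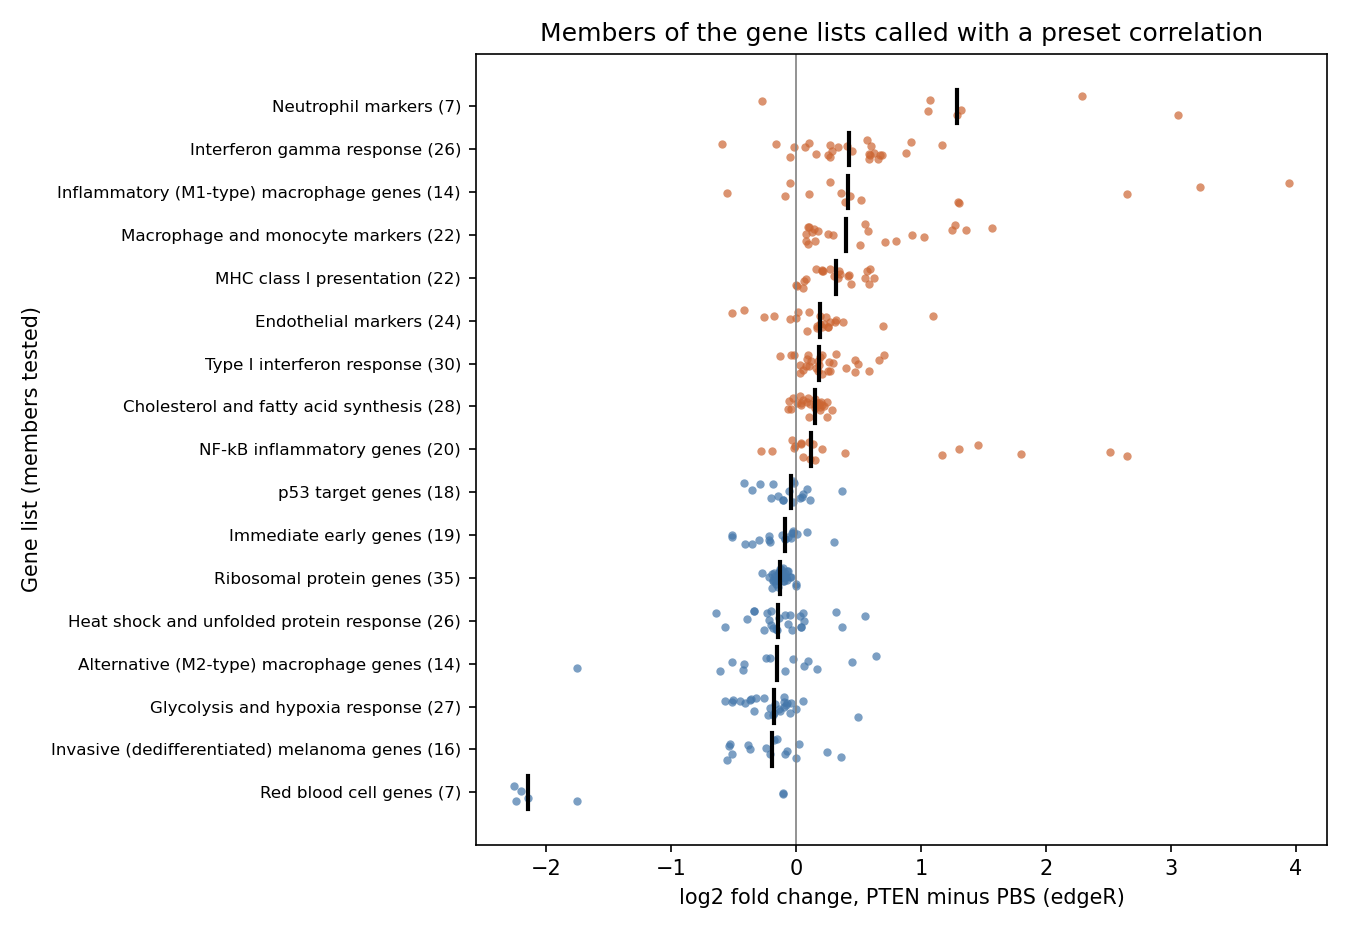
Log2 fold change (PTEN minus PBS, horizontal axis) of every tested member of the 17 lists called at the preset correlation, 1 list per line with the number of tested members; points are genes, black bars the list median, orange lists were called higher and blue lists lower. All 35 ribosomal protein genes lie just below 0, while the M1-type and NF-kB lists hold a few members above 2 and most near 0; none of the 17 calls held with an estimated correlation.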

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

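The tests below on myeloid and on ribosomal protein genes were chosen after those results were seen; the count over splits of the samples was planned. The 8 libraries were grouped in all 35 possible ways into 4 and 4. Of these splits, 5 called at least 2 genes, among them the split by title itself, which called 2. The highest other split called 6. Chance is therefore not excluded as the source of a count of 2. At an unadjusted p under 0.05, 7 of the 35 splits, the split by title included, gave at least the 882 genes of the titles. Another split gave up to 1528, so the libraries also differ along lines other than the titles.

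Several inflammatory myeloid genes were higher in the PTEN libraries: 8 genes of the M1-type, neutrophil and NF-kB lists passed when adjusted over the list alone, with a median log2 fold change of 2.47, a size inflated by their selection on these libraries. More macrophages in an unchanged state cannot be told apart from a change of state: over the lists as fixed, the level of all 14 M1-type genes minus that of the 22 macrophage markers differed by 0.27 log2 units (exact permutation p = 0.257), although C1qa, C1qb and C1qc had only 0.10, 0.15 and 0.10 (SE 0.38, 0.38 and 0.27). For neutrophils, S100a8 and S100a9 together gained 0.89 CPM while the other 6 tested neutrophil markers gained 13.6 CPM, a difference of 12.7 (SE 5.52). Those 6 include Clec4e, Mmp9 and Clec4d, picked for their rise in these libraries, so the comparison cannot decide on neutrophils as the source. The smallness of the first gain rests in part on PBS replicate 4 (5.86 CPM), without which it was 2.21 CPM and the difference 10.9 (SE 5.28). S100a9 was called higher with matching labels only (log2 fold change 3.56), a fit without PBS replicate 4, so neutrophils could be part of it. Other neutrophil genes, named outside the fixed rule, had few counts in the PBS and PTEN libraries. Ly6g and Mpo had 0 in both, S100a8 57 and 51, Retnlg 7 and 5, Ltf 8 and 9, and Cxcr2 9 and 29. Camp, Ngp and Elane had at most 3 in either group. A bacterial product carried by the protein preparation cannot be told apart from an effect of PTEN, since 0 libraries came from tumours given a control protein. An effect of PTEN protein on myeloid cells stays open, as does chance.

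Ribosomal protein genes were lower in PTEN libraries by a median of -0.12 log2 units. By the length implied by counts and FPKM, these genes are short, with a median of 2053 bases against 4577 for all tested genes. Removing the trend of fold change on this length left -0.11. This lay below the central 95% of 10000 random lists matched on expression (-0.05 to 0.05), which treat genes as independent. The implied length need not be that of the expressed transcript, so a trend on transcript length is not excluded. By the treatment label the median was -0.0065 (camera adjusted p = 0.901), so the pattern was absent under that grouping. Without PBS replicate 3, which had the highest level, the median was -0.087. Levels of this list largely ran opposite to those of macrophage markers. They were 1.65 and 0.7 against -1.23 and -1.12 in PBS replicates 3 and 4, but -0.53 against 0.67 in PBS replicate 1. In PTEN replicates 1 and 3 they were -0.93 and -0.87 against 0.89 and 0.79. A different mix of cells in the tumour pieces was not tested and stays open. Chance between libraries stays open too, since the exact permutation p of the list level was 0.114. So does an effect of the treatment, which was not tested apart from chance.

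Among 124 groups of 4 libraries examined for a value far from the others, 5 held one, where chance gives about 6.2. Cd8a was at 0.183 CPM in PTEN replicate 2 against 0.88 to 0.947 CPM in the other PTEN libraries. Ifng had 0.121 CPM in PTEN replicate 1 and 0 in the others. Tyr was at 814 CPM in PBS replicate 3 against 938 to 955 CPM in the other PBS libraries. The type I interferon level was 0.47 in PBS replicate 4 against -0.49 to -0.46 in the other PBS libraries. PBS replicate 1 had 14639 genes with a count against 14375 to 14420 in the other PBS libraries.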

How the results depend on the processing

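The settings fry and the fit without PBS replicate 1 and PTEN replicate 4 were chosen after seeing the data. The 2 genes called, both higher, became 0 by the treatment label, 7 (7 higher) with matching labels only, 0 under the filter of 5 CPM in 4 libraries, and 26 in DESeq2 (23 higher, 3 lower). Limma on FPKM called 0 with a pseudocount of 1 or 0.1 and a mean over 1, and 0 without a filter. At an unadjusted p under 0.05 these zeros stood at 116, 735, 742, 740 and 1080 genes in that order. Under the strict filter and the FPKM filter Marco and Slc13a3 were not tested; the cause of the other changes was not tested. Leaving out 1 library gave 0 to 8 genes changed and 0 to 8 higher, 5 to 9 lists higher and 4 to 9 lower. The other scalings, the fit without a filter, voom with quality weights and the threshold of 1 on the fold change gave 2 or 3 genes higher and 0 lower. Over 19 settings Slc13a3 was called in 12 and Marco in 13, both always higher, with log2 fold changes of 0.51 to 3.46 and 0.54 to 4.58. The value of 0.51 came from log2(FPKM + 1) without a filter. By the treatment label Slc13a3 had 0.55 and Marco 0.54. Slc13a3 had 3.39 with matching labels only (edgeR adjusted p = 0.0553) and 3.22 with the block on replicate number (0.0513).

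The 9 lists called higher and 8 lower became 0 and 0 with an estimated correlation. They were also 0 and 0 with fry, which asks whether the genes of a list move 1 way on balance and compares them with no other genes; its mixed test, for change in either direction, passed 3 lists (adjusted p = 0.0120 for M1-type and M2-type genes, 0.0347 for dendritic cell markers). Exact permutation of list levels gave 0 and 0 too, which says little: at its smallest p of 0.0286, 20 of the 34 lists would have to reach that value for any to pass. Before adjustment 0 of the 34 lists had an exact p under 0.05. By the treatment label 5 lists were called higher and 6 lower, but 4 of the 9 kept their call higher and 0 of the 8 their call lower. Calls ended there without a turn for ribosomal protein (adjusted p = 0.901), p53 (0.873), M2-type (0.0657), endothelial (0.178) and interferon gamma genes (0.345). Without PBS replicate 1 and PTEN replicate 4, 5 lists were called lower. By the treatment label 8 called lists turned direction, with medians of -0.088 for macrophage markers, 0.11 for glycolysis (called higher, adjusted p = 0.00266), 0.0107 for heat shock, -0.12 for MHC class I, -0.12 for cholesterol synthesis (called lower, 4.6e-06), 0.0108 for invasive melanoma genes, 1.85 for red blood cell genes and 0.10 for immediate early genes; with matching labels only, the cholesterol list had -0.061. The Pten difference was never called, and its sign turned in 4 settings, between 0.02 and 0.08 on the log2 scale.

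Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.063, -0.073, -0.15 and -0.17, and 0 of 8 correlated best with their own number. With the replicate number as a block, 3 genes were called (Saa3, Fpr1 and Marco), 3 higher and 0 lower, of which 1 (Marco) was among the 2, with 9 lists higher and 5 lower. The block ended the calls of red blood cell genes (camera adjusted p = 0.104), M2-type genes (0.0598) and p53 targets (0.0902). Depth limits the low genes: Marco rests on 13 counts in the PBS libraries, and Ifng, Tnf and Il6 fell below the filter.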

Other observations

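Some single genes, chosen after their values were seen and tested as no group, went in either direction. Saa3, an acute-phase protein made by macrophages and stroma, was at 0.77 ± 0.39 CPM in PBS and 47.2 ± 33.0 CPM in PTEN libraries, with 0.329 to 1.17 CPM in the PBS and 13.9 to 79.2 CPM in the PTEN libraries; its edgeR adjusted p was 0.399, or 3.41e-08 with the replicate number as a block, and DESeq2 gave 2.88e-13. Fpr1, a receptor for bacterial formyl peptides, had 2 counts in the PBS and 112 in the PTEN libraries (edgeR adjusted p = 0.0570). It was called higher by edgeR without a filter (adjusted p = 0.00757), with the block (0.0370), without PTEN replicate 2 (0.0400) or PTEN replicate 4 (0.0234), by voom with quality weights (0.0303) and by DESeq2 (0.00186). Lcn2, which binds bacterial siderophores, had 11 and 275 counts, but only 0.0676 CPM in PTEN replicate 4, below the 0.527 CPM of PBS replicate 4, against 2.89 to 9.58 CPM in the other PTEN libraries. Slpi, an inhibitor of neutrophil proteases, was at 0.42 ± 0.17 and 1.68 ± 0.64 CPM. Mmp12, a macrophage elastase, was lower, at 22.7 ± 11.3 CPM in PBS and 5.86 ± 2.42 CPM in PTEN libraries (log2 fold change -1.95, SE 0.45, edgeR adjusted p = 0.633, DESeq2 adjusted p = 0.0314). Itgax, an integrin of dendritic cells and macrophages, was at 2.94 ± 1.40 and 0.98 ± 0.60 CPM (-1.58, SE 0.47, edgeR adjusted p = 0.677). With matching labels only, edgeR called Cxcl2, Lcn2, Marco, Il1b, Ccl3, Clec4e and S100a9 higher; S100a8 and S100a9 together stood at 5.86 CPM in PBS replicate 4, which that fit leaves out.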
